A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

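RNA of Saccharomyces cerevisiae W303-1A and of MCY5278, a mutant lacking the transcription factors Msn2 and Msn4, was compared on 16 arrays with 2 dyes each. Every array set RNA of cells given 20 mM KOH against RNA of the same strain given 20 mM KCl for the same time, 10 or 30 min. The 4 groups are wild type and mutant at each time, with 4 arrays per group, and in every group the KOH RNA carried Cy3 on 2 arrays and Cy5 on the other 2. The labels state oligo(dT)-primed cDNA with indirect dye labelling, and 2 biological replicates per condition with a dye swap. They do not say which arrays carry the same extracts, so the arrays were the units, and the p-values are too small wherever arrays share an extract.

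The authors deposited 1 log ratio per gene and array, and the deposited values were read as log2. That base is likely rather than stated. The highest value, 16.268, lies just above the range of a 16-bit scanner in base 2, which ends at 16. In a larger base it lies far above that range. It stood on 1 array, array 1 of wild type at 10 min, and the highest value on any other array was 8.087. The reading thus rests mainly on 1 extreme value, and every fold size depends on the base. Positive values were read as more RNA in KOH than in KCl, also likely rather than stated. The arrays of opposite dye correlated positively within each group, so all 16 were taken to be turned the same way. Scanner, background correction, normalization and the filter behind the empty cells are not given in the sources used here. Between 33.6% and 88.2% of the 6174 features had a value on an array. Systematic names were paired with gene names through the reference table: 5675 features matched and 5158 had a gene name. Near-identical genes such as ENA1 and ENA2, HXT6 and HXT7, PHO11 and PHO12 or paired ribosomal protein genes may not be separated by their probes.

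Because the deposited array medians ran from -0.285 to 0.2615, beyond the limit of 0.1, each array was centred on its median. A linear model in limma 3.58.1 under R 4.3.3 was fitted to all 16 arrays, with 1 coefficient per group and 1 dye term per gene. A gene was tested where each group compared had values on at least 3 arrays and in both dyes. The first 4 comparisons set KOH against KCl in each group, and 4 more took differences between them: mutant minus wild type at each time, and 30 min minus 10 min in each strain. Tests were two-sided limma tests with Benjamini-Hochberg adjustment over the genes tested, and a gene passed at an adjusted p below 0.05. Errors after ± are standard errors of the model, and n is 4 arrays per group unless stated. The number of arrays limits the precision. An exact sign-flip test on 4 arrays cannot go below p = 0.125, so no p-value was taken from one, and sign assignments were only counted.

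The 24 gene lists covered Msn2/Msn4 (STRE) targets, trehalose and glycogen metabolism, calcineurin/Crz1 targets, the phosphate (PHO) regulon, iron and copper uptake, and glucose-repressed and high-affinity hexose transport genes. They also covered Rim101-repressed genes, cell wall integrity (Slt2/Rlm1) genes, oxidative stress (Yap1) genes, heat shock (Hsf1) chaperones, cytosolic ribosomal proteins, ribosome biogenesis, the TCA cycle, the respiratory chain, ergosterol biosynthesis and amino acid biosynthesis (Gcn4) genes. The rest were methionine and sulphur assimilation, H+-ATPases, cAMP/PKA pathway components, G1/S and S phase genes, histones, and markers of MATa cells, MATalpha cells and sporulating diploids. Some genes stand on several lists, so the lists are not independent. Each list was tested against the other genes with limma's cameraPR at a preset correlation of 0.01 and again with a correlation estimated per list, with Benjamini-Hochberg adjustment over the lists of a comparison. Members past the threshold were counted after adjustment over all genes tested and again adjusted over the list alone.

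The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. For each KOH comparison the rule takes the 10 largest rises and the 10 largest falls among genes that passed with the same sign on all measured arrays. For each difference it takes the 8 largest each way. From each list it takes the 4 members with the largest change among those that passed, or the largest member where none did, and MSN2, MSN4, ENA1, PHO84, CTT1 and HSP12 always. Fewer are named in places, in rank order.

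Alternatives were the model without the dye term, on the compared groups only, with the slide series as a block, with robust moderation and with array weights. Further ones used the values as deposited, scale or quantile normalization, genes on all 4 or on at least 2 arrays, the larger slide series only, a 2-fold minimum, and each array left out in turn. Arrays of opposite dye were also averaged into 1 replicate under each of the 16 ways of pairing them within the 4 groups. For the lists, the estimated correlation and limma's rotation test (fry) were used. After seeing the data, 2 were added: centring on the 1477 genes with a value on all 16 arrays, and removal of a trend with coding length on each array. The calculations were also tested on simulated data with 200 changed genes in each comparison. With independent arrays, 44% to 83% of true 2-fold changes passed, and 1.66% to 5.29% of calls were unchanged genes. With 50% of the variance shared within an extract, 22.3% to 28.4% of calls were unchanged genes. Such shares depend on the number of changed genes, so they are not the shares among the real calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.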

Results

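The arrays measured how RNA levels of budding yeast changed after a shift to alkaline medium, made with 20 mM KOH and compared with the same concentration of KCl. Wild type W303-1A and the msn2 msn4 mutant MCY5278 were sampled at 10 and 30 min, with 4 arrays in each of the 4 groups. Msn2 and Msn4 are related transcription factors that bind the stress response element (STRE), and protein kinase A (PKA) keeps them out of the nucleus. The series concerns the part of this kinase pathway in the alkaline response. The mutant lets the response be compared with and without these 2 factors. Values are log2 ratios of KOH over KCl, with base and direction likely rather than stated, after centring of each array on its median.

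An array held values for 2073 to 5443 genes, and 1477 genes had a value on all 16 arrays. At least 3 arrays gave a value for 2670 genes in wild type at 10 min, 3042 in the mutant at 10 min, 4288 in wild type at 30 min and 4234 in the mutant at 30 min. Between arrays of a group, correlations across genes, which are not independent, ran from 0.542 to 0.865. The 4 arrays of a group stand for 2 biological replicates, so every p-value is too small. The total count of each comparison is given with its range over the 16 ways of pairing the arrays, while counts within lists, but for STRE targets at 10 min, and overlaps of the strains are not. Each ratio compares a strain with itself, so it shows no difference in level between the strains. MSN2 had a value on all 8 mutant arrays and MSN4 on 5 of 8, although the labels give both as deleted there, and what their probes measured is not known. MSN2 stood at -0.09 ± 0.14 (adjusted p = 0.659) in wild type and -0.27 ± 0.14 (adjusted p = 0.141) in the mutant at 10 min. MSN4 stood at 0.05 ± 0.11 (adjusted p = 0.775) in wild type at 10 min and at -0.27 ± 0.13 (adjusted p = 0.119, n = 3) in the mutant at 30 min.

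In wild type at 10 min, which shows the first response to alkali, calcineurin/Crz1 targets and genes of carbohydrate storage rose and genes of ribosome assembly fell. PHO89, a sodium-coupled phosphate transporter, rose by 4.29 ± 0.20, or 19.6-fold, and CMK2, a calmodulin-dependent kinase, by 3.93 ± 0.20. Further large rises were those of YGR067C (5.16 ± 0.95, n = 3), BOP2 (4.59 ± 0.21), YOR385W (4.22 ± 0.18) and BDH2 (4.15 ± 0.25, n = 3). They were followed by PUN1 (4.09 ± 0.24), RGI1 (3.92 ± 0.22), AIM17 (3.76 ± 0.18) and NCE103, the carbonic anhydrase gene (3.76 ± 0.22). The 3 arrays of YGR067C stood at 7.83, 3.61 and 3.59. Genes that act in ribosome assembly were among the largest falls, with ENP1 at -2.34 ± 0.19 (n = 3), NHP2 at -2.14 ± 0.19, EBP2 at -2.05 ± 0.19 and CIC1 at -1.93 ± 0.34 (n = 3). RLP24 stood at -1.77 ± 0.21, with 1 array at -2.55 and the others between -1.59 and -1.44. TRM8, a tRNA methyltransferase subunit, fell by 2.37 with an error of 0.64, and rested on 1 array at -6.53 while the others lay between -1.19 and -0.87. HPT1, which salvages purines, fell by 2.08 with an error of 0.28. All of these had adjusted p of 0.00901 or less and the same sign on every measured array.

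Every tested calcineurin/Crz1 target rose in wild type at 10 min: 11 of 11, also 11 adjusted over the list alone. Their median was 2.98 and the camera adjusted p was 4.45e-34, or 2.93e-14 with an estimated correlation. Of 30 tested STRE targets, 28 rose (28 adjusted over the list alone), with a median of 2.23. Their camera adjusted p was 6.17e-35, or 0.00042 with an estimated correlation. GLC3, the glycogen branching enzyme, led them at 3.68 ± 0.21, followed by MSC1 at 3.60 ± 0.14. Trehalose and glycogen genes rose in 13 of 13 cases, 13 also adjusted over the list alone. This list had a median of 2.49 and a camera adjusted p of 2.33e-19, or 0.00042 with an estimated correlation. GSY1, a glycogen synthase, stood at 3.74 ± 0.24. HSP12, a classic STRE target, had values on 2 arrays only, 4.00 and 3.27, and was not tested. CTT1, cytosolic catalase, rose by 0.51 ± 0.14 (adjusted p = 0.00863) with 1 array at 1.17 and the others between 0.23 and 0.39.

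Genes for growth on poor sugar supply rose with them. Of 10 glucose-repressed and hexose transport genes, 7 rose, also 7 adjusted over the list alone. Their camera adjusted p was 6.38e-07, or 0.0269 with an estimated correlation. HXT2, a high-affinity glucose transporter, rose by 3.71 ± 0.24 and HXK1, a hexokinase, by 2.88 ± 0.15. Among 17 cAMP/PKA pathway components, 11 rose, or 11 higher and 1 lower adjusted over the list alone. This list had a camera adjusted p of 8.45e-06, or 0.0269 with an estimated correlation. GPA2, a G protein alpha subunit upstream of adenylate cyclase, rose by 3.09 ± 0.15 and YAK1, a kinase that opposes growth, by 2.93 ± 0.13. Methionine and sulphur genes rose in 9 of 17 cases, 9 also adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.438 with an estimated correlation). STR3 led them at 2.37 ± 0.28 (n = 3), before the methylmethionine permease MMP1 at 1.95 ± 0.19.

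Ribosome genes fell broadly at 10 min in wild type. Of 111 cytosolic ribosomal protein genes, 106 fell, also 106 adjusted over the list alone. Their median was -0.97 and the camera adjusted p was 1.62e-33, or 0.0269 with an estimated correlation. RPS9B stood at -1.67 ± 0.15 and RPS9A at -1.53 ± 0.21. Ribosome biogenesis genes fell in 26 of 32 cases and rose in 2, with the same counts adjusted over the list alone. That list had a median of -0.88 and a camera adjusted p of 8.61e-07, or 0.0395 with an estimated correlation. Ergosterol biosynthesis fell in 8 of 20 genes, 8 also adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.601 with an estimated correlation), with ERG5 at -1.36 ± 0.14 (n = 3) and ERG3 at -1.10 ± 0.14.

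The other lists did not pass as a whole in wild type at 10 min. Counts here were the same adjusted over the list alone except where given. Cell wall integrity genes had 8 higher of 12 (camera adjusted p = 0.0545), led by GSC2, also called FKS2, a glucan synthase, at 1.90 ± 0.22. The PHO regulon had 2 higher and 4 lower of 13 (camera adjusted p = 0.775), with PHO12, an acid phosphatase, at -0.95 ± 0.19. The transporter PHO84 stood at -0.89 ± 0.17, where 1 array stood at -0.20 and the others between -1.14 and -1.08. Amino acid biosynthesis had 11 higher and 4 lower of 29, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.463), with ARG3 at 1.14 ± 0.14. Iron and copper genes had 2 higher and 2 lower of 9 (camera adjusted p = 0.568), and Yap1 genes 4 higher and 1 lower of 14 (camera adjusted p = 0.566). Hsf1 chaperones had 5 higher and 1 lower of 13 (camera adjusted p = 0.185), and HSP104, a disaggregase, rose by 2.16 ± 0.19. TCA cycle genes had 6 higher and 2 lower of 14 (camera adjusted p = 0.356), respiratory chain genes 4 higher of 14 (camera adjusted p = 0.516), and G1/S genes 3 lower of 5 (camera adjusted p = 0.0749).

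H+-ATPase genes had 1 higher and 3 lower of 14 in wild type at 10 min, the same adjusted over the list alone (camera adjusted p = 0.528). STV1, a subunit of the vacuolar-type H+-ATPase, rose by 1.08 ± 0.14. PMA1, the plasma membrane proton pump, stood at -0.74 ± 0.20, with 1 array at -0.51 and the others between -0.84 and -0.80. In limma 0 of 9 histone genes passed, 1 at an unadjusted p below 0.05 (camera adjusted p = 0.568). Lists with fewer than 3 tested genes got no list test. They were Rim101-repressed genes, with 0 of 1 past limma's test (0 unadjusted), MATa markers with 0 of 1 (0 unadjusted) and MATalpha markers with 0 of 2 (0 unadjusted). Sporulation markers had 1 lower of 2, also 1 adjusted over the list alone: SPS4, at -0.47 ± 0.15 (adjusted p = 0.0202).

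In total 582 genes were higher and 558 lower among 2670 tested in wild type at 10 min, and 341 of these 1140 changed at least 2-fold. The balance of rises and falls depends on the scaling. With the values as deposited, under scale or quantile normalization, or centred on the genes measured on all 16 arrays, the last chosen after seeing the data, 535 to 711 were higher and 445 to 612 lower. Averaging arrays of opposite dye gave 666 to 1281 genes. The larger slide series alone gave 834, and fitting the slide series as a block gave 1147. ENA1, the sodium pump gene, had a value on 1 array only, 3.25, and could not be tested.

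The mutant at 10 min shows what alkali does without Msn2 and Msn4. BOP2 rose by 5.74 ± 0.21, PHO89 by 4.99 ± 0.20 (31.7-fold), CMK2 by 4.60 ± 0.20 and NCE103 by 4.47 ± 0.22. Next, PUN1 rose by 4.39 ± 0.24, YOR385W by 4.30 ± 0.18, YMR316C-A by 4.25 ± 0.40, HXT2 by 4.00 ± 0.24, RCN2, a calcineurin regulator, by 3.70 ± 0.20 and GYP7 by 3.67 ± 0.11. The largest falls included the ribosome assembly genes UTP4 (-2.49 ± 0.22, n = 3), UTP9 (-2.47 ± 0.21, n = 3) and CIC1 (-2.46 ± 0.29). Then came HPT1 (-2.32 ± 0.32, n = 3), ECM1 (-2.26 ± 0.34, n = 3), HGH1 (-2.17 ± 0.22, n = 3) and the S phase cyclin CLB6 (-2.15 ± 0.50, n = 3). All had adjusted p of 0.00721 or less and the same sign on every measured array.

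Calcineurin/Crz1 targets rose in 12 of 12 cases in the mutant at 10 min, 12 also adjusted over the list alone (median 2.81). This list had a camera adjusted p of 4.13e-47, or 5.78e-19 with an estimated correlation. STRE targets rose in 17 of 25 cases, 17 also adjusted over the list alone, with a median of 0.70. Their camera adjusted p was 3.59e-06, but adjusted p = 0.221 with an estimated correlation. XBP1, a repressor of cell cycle genes, rose by 2.16 ± 0.17 (n = 3) and YAK1 by 1.77 ± 0.13. Trehalose and glycogen genes rose in 5 of 8 cases, or 6 adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.414 with an estimated correlation). Glucose-repressed genes rose in 6 of 10 cases, or 7 adjusted over the list alone (camera adjusted p = 0.000309, and adjusted p = 0.122 with an estimated correlation). Among them ALD4, an aldehyde dehydrogenase, rose by 2.63 ± 0.22. For cAMP/PKA components the counts were 3 higher of 10, or 2 adjusted over the list alone (camera adjusted p = 0.00332, and adjusted p = 0.122 with an estimated correlation). GPA2 rose by 3.00 ± 0.15. Methionine and sulphur genes rose in 9 of 18 cases, or 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000321, and adjusted p = 0.147 with an estimated correlation). The sulphate permease gene SUL1 rose by 3.03 ± 0.30 (n = 3). Amino acid biosynthesis had 11 higher and 3 lower of 29, the same adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.769 with an estimated correlation). ARG3 rose by 2.05 ± 0.14, with 1 array at 2.36 and the others between 1.92 and 1.97.

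Ribosomal protein genes fell in 111 of 118 cases in the mutant at 10 min, or 113 adjusted over the list alone. Their median was -0.86 and the camera adjusted p 1.13e-30, but adjusted p = 0.055 with an estimated correlation. The 1 member that rose was RPS29A, at 0.75 ± 0.18 (adjusted p = 0.00509), named after its value was seen. Ribosome biogenesis genes fell in 45 of 51 cases, or 45 lower and 1 higher adjusted over the list alone (median -1.20). That list had a camera adjusted p of 1.54e-16, or 0.00388 with an estimated correlation. G1/S and S phase genes fell in 6 of 11 cases, 6 also adjusted over the list alone (camera adjusted p = 0.0119, or 0.0195 with an estimated correlation). MCD1, a cohesin subunit, stood at -1.76 ± 0.20 (n = 3). RIM8, of the alkaline signalling pathway and the 1 tested Rim101-repressed gene, rose by 0.70 ± 0.19 (adjusted p = 0.0104, 1 of 1 also adjusted over the list alone), against 0.07 ± 0.22 (adjusted p = 0.823, n = 3) in wild type. The difference between the strains, 0.62 ± 0.29, did not pass among all genes (adjusted p = 0.465) but passed as the list's 1 tested gene when adjusted over the list alone, which is an unadjusted test. Sporulation markers had 1 higher of 3 in the mutant at 10 min, also 1 adjusted over the list alone (camera adjusted p = 0.916), namely SPS1 at 0.95 ± 0.30 (adjusted p = 0.0408, n = 3).

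The mutant had 565 genes higher and 544 lower among 3042 tested at 10 min, and 279 of these 1109 changed at least 2-fold. Over the same scalings 472 to 693 were higher and 522 to 668 lower. With arrays of opposite dye averaged, the count ran from 483 to 1307. It was 668 of 2046 tested on the larger slide series alone, 1113 of 3000 with the block and 647 of 2049 without array 4 of this group.

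The difference between the strains at 10 min addresses which part of the early response differs without Msn2 and Msn4. STRE targets and the genes that store glucose as trehalose and glycogen rose less in the mutant, while calcineurin/Crz1 targets did not pass a test of difference. PGM2, a phosphoglucomutase, differed by -2.75 ± 0.30 between mutant and wild type, a 6.72-fold smaller response (adjusted p = 4.72e-05). MSC1 differed by -2.20 ± 0.22, GLC3 by -2.02 ± 0.32 and TPS2, which makes trehalose, by -1.95 ± 0.27. HXK1 differed by -1.92 ± 0.21, STF2 by -1.87 ± 0.32 and GSY2, a glycogen synthase, by -1.63 ± 0.33, and each of these had an adjusted p of 0.0136 or less. NSA1, a ribosome assembly gene, rose in wild type by 0.92 ± 0.19 and fell in the mutant, at -0.83 ± 0.22, a difference of -1.75 ± 0.29. Higher in the mutant were VHT1, a biotin transporter (1.10 ± 0.21, adjusted p = 0.009), and ARG3, an arginine biosynthesis enzyme (0.92 ± 0.20, adjusted p = 0.0267).

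Of 22 STRE targets tested for the difference at 10 min, 15 were lower in the mutant, or 17 adjusted over the list alone. Their median was -1.26 and the camera adjusted p 5.7e-56, or 4.38e-08 with an estimated correlation. A further 8 STRE targets with values in wild type had too few in the mutant, and these had a median rise of 2.54 in wild type against 1.61 for the tested ones. The trehalose and glycogen list, which shares members with the STRE list, had 6 of 7 lower (6 adjusted over the list alone). It had a median of -1.63 and a camera adjusted p of 1.68e-27, or 1.42e-08 with an estimated correlation. The 21 genes lower in the mutant held 15 of the 22 tested STRE targets among 2361 genes. Two-sided, Fisher's exact p was 3.15e-29, but genes are not independent and these calls take the arrays as units. With arrays of opposite dye averaged, 3 to 14 of the 22 were lower. The other 6 of the 21 genes, named after their values were seen where the rule did not take them, were STF2, NSA1, MRK1 (-1.50 ± 0.26), OSH2 (-1.18 ± 0.21), USV1 (-1.10 ± 0.17) and YPL247C (-0.99 ± 0.18). Calcineurin/Crz1 targets had 0 of 11 past the limma test, 2 at an unadjusted p below 0.05 and 0 adjusted over the list alone. Their median was 0.21 and the camera adjusted p 0.19.

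Chaperones of the Hsf1 list differed in 3 of 13 cases, all lower and 3 also adjusted over the list alone (camera adjusted p = 0.000922, and adjusted p = 0.324 with an estimated correlation). HSP104 differed by -1.46 ± 0.26 and HSP78 by -1.45 ± 0.26, both of them STRE targets too. Among cAMP/PKA components 1 of 10 was lower, 1 also adjusted over the list alone (camera adjusted p = 0.000922, and adjusted p = 0.0869 with an estimated correlation). It was YAK1, also a STRE target, at -1.16 ± 0.18. Glucose-repressed genes had 1 lower of 7, 1 also adjusted over the list alone, namely HXK1, another STRE target. Their median was 0.04, their mean -0.26 and the list test towards lower values (camera adjusted p = 0.00555, and adjusted p = 0.277 with an estimated correlation). Ribosomal protein genes had 0 of 110 past the limma test, 3 at an unadjusted p below 0.05 and 0 adjusted over the list alone. Their median was 0.14 (camera adjusted p = 0.0408, and adjusted p = 0.738 with an estimated correlation), but 0.00 under scale normalization and -0.02 with a trend with coding length removed, an alternative chosen after seeing the data. CTT1 differed by -0.65 ± 0.20 and did not pass (adjusted p = 0.198).

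**Figure D1:**
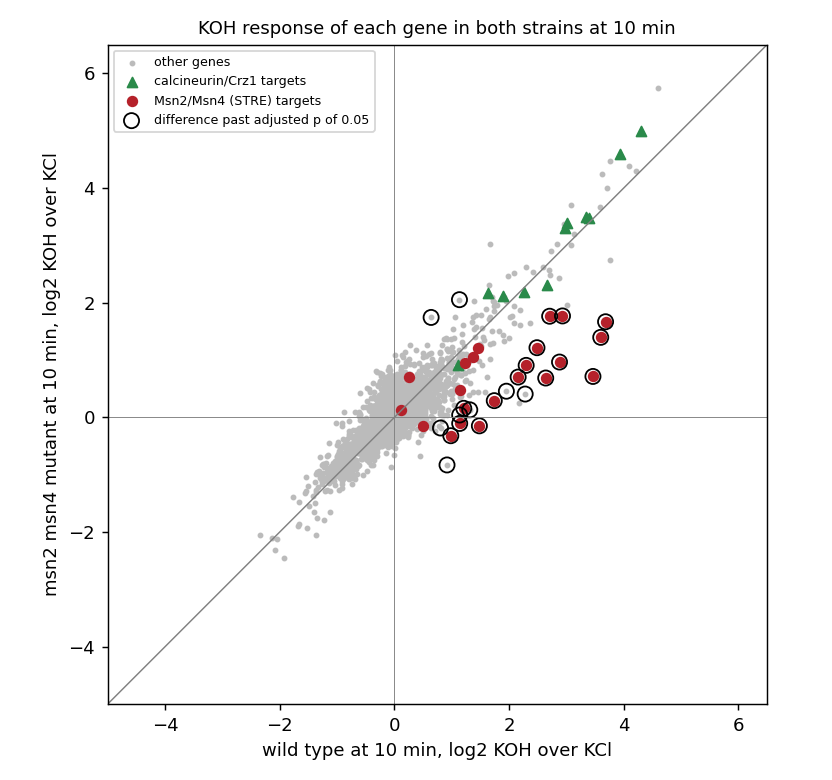
Each point is 1 of 2361 genes tested in both strains, with the log2 ratio of KOH over KCl at 10 min in wild type on the x axis and in the mutant on the y axis, and circles mark the 23 genes whose difference passed. Of the 22 STRE targets (red), 15 lie circled under the diagonal, while none of the 11 calcineurin/Crz1 targets (green) is circled.

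In total 2 genes were higher and 21 lower in the mutant at 10 min among 2361 tested, with 251 at an unadjusted p below 0.05. The scalings gave 1 to 15 higher and 11 to 28 lower. Pairs of arrays averaged over the dyes gave 4 to 26 genes, with 3 to 14 of the 22 STRE targets lower and their median between -1.26 and -1.25. That median could hardly move, since every pairing averages the same arrays of a group. Arrays 1 with 2 and 3 with 4, the pairs whose residuals correlated positively in every group, gave 5 genes. With this pairing 4 of the 22 STRE targets were lower, with a median of -1.25. The larger slide series alone gave 8 of 1834 genes tested and the block 25 of 2361. Without array 4 of the mutant there were 10 of 1843 tested, and without array 4 of wild type 36 of 2337. The difference correlated with coding length across genes, which are not independent (Spearman's rho = -0.396), and 25 genes passed with that trend removed.

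By 30 min in wild type, the comparison of the later response, calcineurin/Crz1 targets rose and ribosomal protein genes fell. SNZ1, of vitamin B6 biosynthesis, rose by 4.70 ± 0.20 (25.9-fold) and its neighbour SNO1 by 2.63 ± 0.13. PHO89 stood at 4.07 ± 0.20, YAT2, a carnitine acetyltransferase, at 3.84 ± 0.21 (n = 3), and BOP2 at 3.83 ± 0.21. NCE103 rose by 3.62 ± 0.22, CIT2, the peroxisomal citrate synthase, by 3.54 ± 0.14 and SER3, of serine biosynthesis, by 2.97 ± 0.18. TMT1, a methyltransferase, followed at 2.85 ± 0.28 and SRY1, which breaks down hydroxyaspartate, at 2.65 ± 0.14. The peptide transporter gene PTR2 fell most, at -3.48 ± 0.20, followed by YRO2 (-2.28 ± 0.19), UTP20 (-2.24 ± 0.23) and CHA1, which degrades serine (-2.23 ± 0.28, n = 3). Then came SNU13 (-2.20 ± 0.19), MAK21 (-2.15 ± 0.28) and NOP56 (-2.14 ± 0.22), which like UTP20 act in ribosome assembly. All had adjusted p of 0.000227 or less and the same sign on every measured array.

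Of 123 ribosomal protein genes, 122 fell in wild type at 30 min, also 122 adjusted over the list alone. Their median was -1.44, or -1.51 with the coding length trend removed, and RPS9B fell most, at -2.14 ± 0.15. The list's camera adjusted p was 1.29e-89, or 0.000112 with an estimated correlation. Ribosome biogenesis genes fell in 39 of 56 cases and rose in 1, or 43 and 1 adjusted over the list alone. That list had a camera adjusted p of 1.07e-11, or 0.0284 with an estimated correlation. Calcineurin/Crz1 targets rose in 11 of 12 cases, 11 also adjusted over the list alone. They had a median of 1.44 and a camera adjusted p of 1.18e-13, or 2.7e-05 with an estimated correlation. Cell wall integrity genes rose in 10 of 14 cases, 10 also adjusted over the list alone (camera adjusted p = 2.75e-05, or 0.0446 with an estimated correlation). GSC2 stood at 2.53 ± 0.22 and PRM5 at 1.98 ± 0.14. Amino acid biosynthesis genes rose in 21 of 30 cases and fell in 1, the same adjusted over the list alone, with a median of 0.97. Their camera adjusted p was 3.18e-12, but adjusted p = 0.0876 with an estimated correlation. Behind SER3 stood ARG1, of arginine biosynthesis, at 2.24 ± 0.14.

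STRE targets rose in 15 of 29 cases in wild type at 30 min, also 15 adjusted over the list alone, led by the glucokinase GLK1 (1.79 ± 0.16). Their median was 0.64 and the camera adjusted p 5.41e-06, but adjusted p = 0.242 with an estimated correlation. The PHO regulon rose in 7 of 15 cases, or 9 adjusted over the list alone (camera adjusted p = 0.00045, and adjusted p = 0.223 with an estimated correlation). Methionine and sulphur genes rose in 12 of 22 cases, or 14 adjusted over the list alone (camera adjusted p = 0.000521, and adjusted p = 0.223 with an estimated correlation). Hsf1 chaperones fell in 10 of 15 cases, 10 also adjusted over the list alone (camera adjusted p = 0.000955, and adjusted p = 0.242 with an estimated correlation), with SSA2 at -1.11 ± 0.16.

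Other lists did not pass as a whole in wild type at 30 min. Iron and copper genes were higher in 6 of 18 cases and lower in 1 (camera adjusted p = 0.074), with HMX1, a haem oxygenase, at 2.30 ± 0.15. Of 10 trehalose and glycogen genes, 5 were higher (camera adjusted p = 0.074). PMA1 stood at -1.39 ± 0.20 on an H+-ATPase list with 3 lower of 15, or 2 adjusted over the list alone (camera adjusted p = 0.497). The respiratory chain had 4 lower of 26 (camera adjusted p = 0.497), with CYT1, cytochrome c1, at -0.82 ± 0.16. Of 3 MATa markers 1 was lower, also 1 adjusted over the list alone, namely STE6 at -0.79 ± 0.16 (n = 3). This list had a median of 0.06, a mean of -0.19 and a test towards lower values (camera adjusted p = 0.591).

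In total 824 genes were higher and 806 lower among 4288 tested in wild type at 30 min, and 481 of these 1630 changed at least 2-fold. Depending on the scaling, 748 to 988 were higher and 669 to 873 lower. Over the pairings of opposite dyes the count ran from 689 to 1824, and it was 1161 on the larger slide series and 1638 with the block.

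In the mutant at 30 min, PHO89 stood highest at 4.32 ± 0.20 (20.0-fold), followed by SNZ1 at 4.25 ± 0.20, BOP2 at 4.09 ± 0.22 and CIT2 at 3.37 ± 0.14. Further rises were those of GSC2 at 3.36 ± 0.22, NCE103 at 3.31 ± 0.22, the sodium pump ENA2 at 2.77 ± 0.15 and the vacuolar protease PRB1 at 2.70 ± 0.18. PTR2 again fell most, at -3.41 ± 0.20. Most of the other large falls were ribosomal protein genes: RPS22A at -2.96 ± 0.18, RPL22A at -2.92 ± 0.17 (n = 3), RPS9B at -2.79 ± 0.15, RPS10A at -2.69 ± 0.17 and RPL27B at -2.60 ± 0.16. YRO2 stood at -2.96 ± 0.19, with 1 array at -4.00 and the others between -2.77 and -2.52. The highest adjusted p among these genes was 2.81e-07, and each had the same sign on every measured array.

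All 123 tested ribosomal protein genes fell in the mutant at 30 min, 123 also adjusted over the list alone. Their median was -1.95, or -1.89 with the coding length trend removed. The list's camera adjusted p was 1.06e-148, or 1.33e-07 with an estimated correlation. Calcineurin/Crz1 targets rose in 12 of 12 cases, 12 also adjusted over the list alone (median 1.77). Their camera adjusted p was 1.17e-18, or 1.33e-07 with an estimated correlation. Cell wall integrity genes rose in 12 of 14 cases and fell in 1, the same adjusted over the list alone, with CRH1, a chitin transglycosylase, at 1.93 ± 0.18. This list had a camera adjusted p of 9.73e-08, or 0.005 with an estimated correlation. Iron and copper genes rose in 10 of 18 cases, or 11 higher and 1 lower adjusted over the list alone. They had a camera adjusted p of 0.00242, or 0.00215 with an estimated correlation. HMX1 stood at 2.10 ± 0.15 and the ferric reductase FRE1 at 1.47 ± 0.15. Amino acid biosynthesis genes rose in 21 of 29 cases and fell in 2, the same adjusted over the list alone (camera adjusted p = 1.63e-10, and adjusted p = 0.151 with an estimated correlation). SER3 rose by 2.27 ± 0.18 and CPA1, of arginine biosynthesis, by 2.03 ± 0.13. The PHO regulon rose in 8 of 14 cases, or 9 adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.175 with an estimated correlation), and PHO84 stood at 1.21 ± 0.18. Methionine and sulphur genes rose in 12 of 21 cases, 12 also adjusted over the list alone (camera adjusted p = 0.000556, and adjusted p = 0.21 with an estimated correlation).

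In the mutant at 30 min, STRE targets rose in 13 of 35 cases and fell in 3, the same adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.0214, and adjusted p = 0.721 with an estimated correlation). DDR48 led them at 1.22 ± 0.14, HSP12 stood at 0.16 ± 0.19 (adjusted p = 0.526), and CTT1 was lower, at -0.53 ± 0.15 (adjusted p = 0.00893). Ribosome biogenesis genes fell in 23 of 43 cases and rose in 4, or 24 and 4 adjusted over the list alone (camera adjusted p = 0.000745, and adjusted p = 0.271 with an estimated correlation). Hsf1 chaperones fell in 9 of 15 cases, or 11 adjusted over the list alone (camera adjusted p = 0.0402, and adjusted p = 0.633 with an estimated correlation). Ergosterol genes rose in 10 of 23 cases and fell in 1, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.721 with an estimated correlation), with the squalene synthase ERG9 at 0.92 ± 0.17. Of 17 cAMP/PKA components, 10 rose, or 11 adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.302 with an estimated correlation). PDE1, a cAMP phosphodiesterase, rose by 1.42 ± 0.19 and IRA1, which restrains Ras, by 1.15 ± 0.19. The repressor gene NRG1, 1 of 2 tested Rim101-repressed genes, fell by 1.01 with an error of 0.12 (adjusted p = 6.88e-05). Yap1 genes passed in 3 cases higher and 4 lower of 14, the same adjusted over the list alone. That list had a median of 0.12, a mean of -0.07 and a test towards lower values (camera adjusted p = 0.802). On the MATa list BAR1 rose by 0.76 ± 0.17, and on the sporulation list SPS4 stood at -0.94 ± 0.16.

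**Figure D2:**
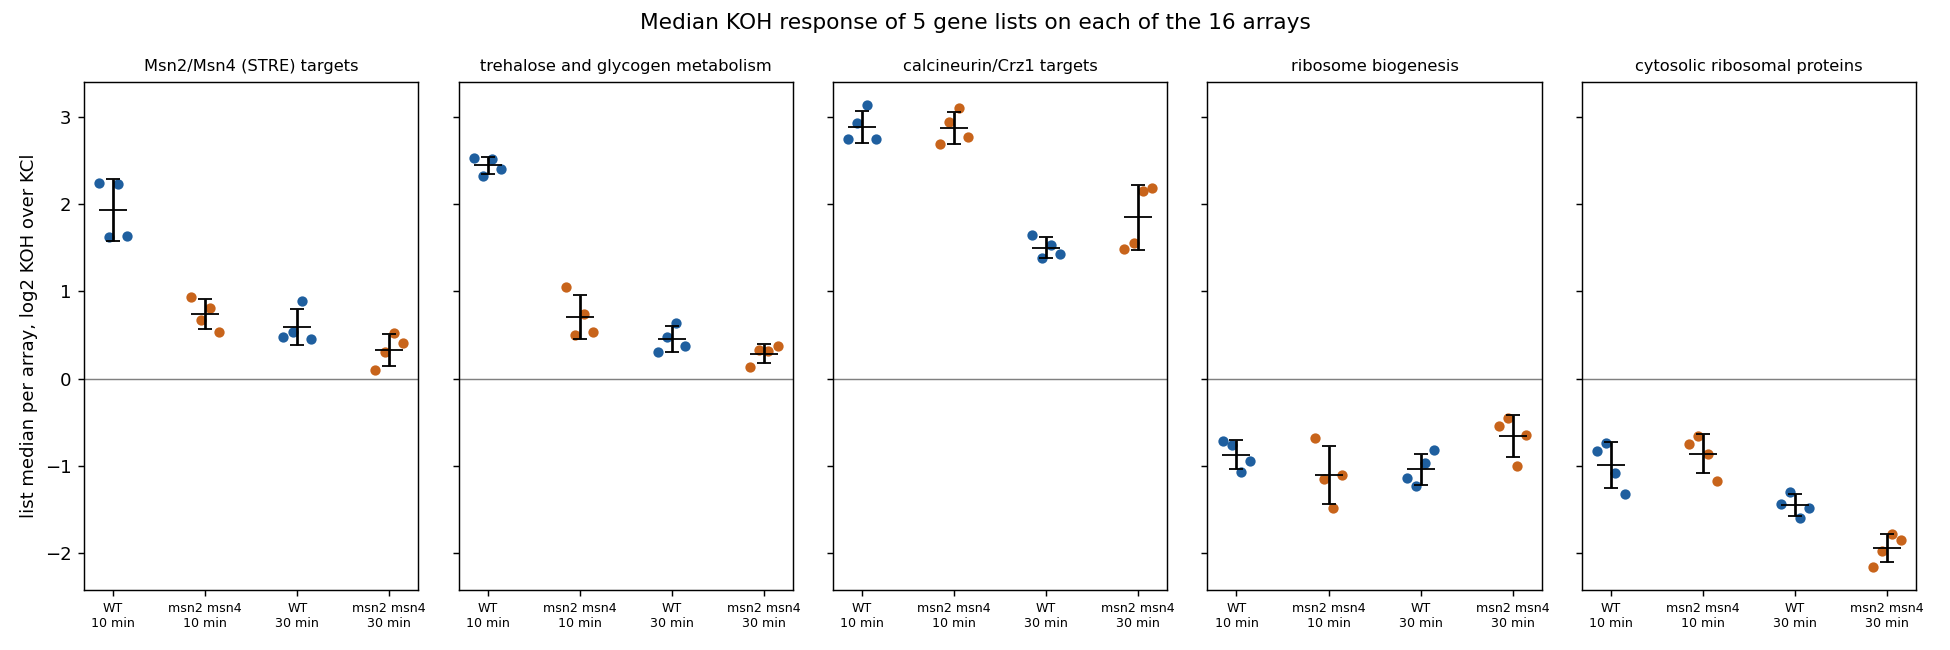
Each point is the median log2 ratio of KOH over KCl of a gene list on 1 array, for wild type (blue) and mutant (orange) at 10 and 30 min, with the mean and SD of the 4 arrays of a group, over the genes tested in that group. STRE targets stand highest on the wild-type arrays at 10 min, while calcineurin/Crz1 targets are high in both strains and ribosomal protein genes are below 0 on all 16 arrays.

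In total 932 genes were higher and 810 lower among 4234 tested in the mutant at 30 min, and 505 of these 1742 changed at least 2-fold. Between the scalings, 845 to 1014 were higher and 737 to 761 lower. The pairings of opposite dyes gave 601 to 1929 genes. A fit on this group's arrays alone gave 810, the larger slide series 1185 and the block 1740.

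The strain difference at 30 min asks whether the later response differs without Msn2 and Msn4. Higher in the mutant were long genes such as USO1, of vesicle transport (1.81 ± 0.34, adjusted p = 0.0433), and PRP8, of the spliceosome (1.52 ± 0.27, adjusted p = 0.0319). Next came NUP188, of the nuclear pore (1.38 ± 0.22, adjusted p = 0.0264), and TOM1, a ubiquitin ligase (1.35 ± 0.23, adjusted p = 0.0209). Lower were short genes such as YOR289W (-1.28 ± 0.23, adjusted p = 0.0351), RPL22A (-1.17 ± 0.22, adjusted p = 0.0403) and RPL25 (-1.12 ± 0.22, adjusted p = 0.035). PYK2, a pyruvate kinase, stood at -1.15 ± 0.23 (adjusted p = 0.0351). The median coding length was 3822 bases for genes higher in the mutant, 891 for those lower and 1201.5 for all tested genes. The difference correlated with coding length across genes, which are not independent (Spearman's rho = 0.533).

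Among the lists, 4 of 122 ribosomal protein genes were lower in the mutant at 30 min, or 62 adjusted over the list alone. Their median was -0.53, or -0.39 with the coding length trend removed, and the camera adjusted p 1.77e-22, but adjusted p = 0.245 with an estimated correlation. STRE targets had 0 of 29 past the limma test, 7 at an unadjusted p below 0.05 and 5 lower adjusted over the list alone. Their median was -0.32 (camera adjusted p = 0.00243, and adjusted p = 0.707 with an estimated correlation). For calcineurin/Crz1 targets limma passed 0 of 12, with 4 at an unadjusted p below 0.05 and 4 higher adjusted over the list alone (camera adjusted p = 0.00574, and adjusted p = 0.245 with an estimated correlation). Iron and copper genes had 1 higher of 17, FRE1, or 3 adjusted over the list alone (camera adjusted p = 0.0305, and adjusted p = 0.113 with an estimated correlation). Ergosterol genes had 1 higher of 23, ERG11, or 3 adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.72 with an estimated correlation). FRE1 differed by 1.04 ± 0.21 and ERG11 by 0.79 ± 0.17. Limma passed 0 of 14 cell wall integrity genes, with 4 at an unadjusted p below 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.606 with an estimated correlation). It also passed 0 of 42 ribosome biogenesis genes, with 8 at an unadjusted p below 0.05, or 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00578, and adjusted p = 0.606 with an estimated correlation).

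In total 29 genes were higher and 11 lower in the mutant at 30 min among 3978 tested, with 808 at an unadjusted p below 0.05. Here the scalings gave 19 to 74 higher and 7 to 32 lower, with 74 and 12 as deposited but 21 and 21 centred on the genes measured on all 16 arrays. Averaging arrays of opposite dye gave 0 to 252 genes in limma, and 0 under 12 of the 16 pairings (274 to 673 at an unadjusted p below 0.05). The larger slide series alone gave 0 in limma (799 at an unadjusted p below 0.05) and the block 35. Leaving out array 1 or array 2 of either strain also gave 0 (467 to 658 at an unadjusted p below 0.05). Leaving out array 3 of wild type gave 259 genes and array 4 of wild type 73. Removal of the coding length trend, chosen after seeing the data, left 2 of 3816 genes with a known length, namely PHD1 (1.05 ± 0.17 before removal) and TPO4 (-1.03 ± 0.21).

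**Figure D3:**
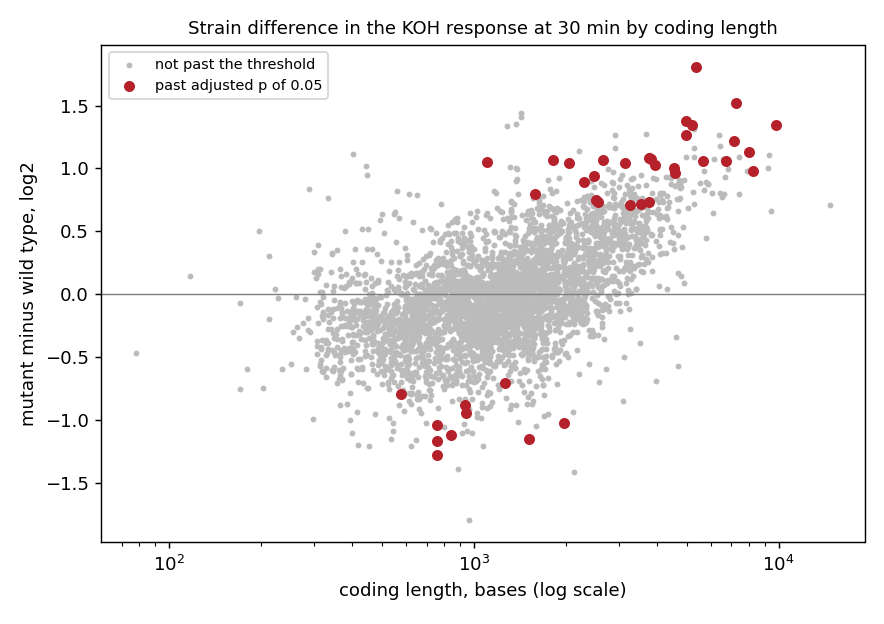
Each point is a gene tested in both strains at 30 min, with its coding length in bases on a log x axis and its mutant minus wild type difference in log2 on the y axis. Red marks 39 of the 40 genes past the threshold, those with a known length, and the higher ones are long (median 3822 bases) and the lower ones short (median 891 bases).

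The change from 10 to 30 min in wild type shows which parts of the response were brief. Glycogen synthase GSY1 was lower at 30 min by a difference of -3.68 ± 0.36, BDH2 by -4.22 ± 0.34 and YOR385W by -3.30 ± 0.25. HXT2 differed by -3.20 ± 0.33, HAL5, a kinase of salt tolerance, by -2.89 ± 0.31 and HXK1 by -2.88 ± 0.21. Higher at 30 min were SER3 (2.18 ± 0.25), SNZ1 (1.97 ± 0.28), HPT1 (1.92 ± 0.39) and OPI3, of phosphatidylcholine synthesis (1.81 ± 0.31). All of these had adjusted p of 0.00223 or less.

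STRE targets were lower at 30 min than at 10 min in 21 of 27 cases in wild type and higher in 1, or 21 and 2 adjusted over the list alone. Their median difference was -1.36 and the camera adjusted p 4.62e-19, or 0.0128 with an estimated correlation. Trehalose and glycogen genes were lower in 9 of 10 cases, 9 also adjusted over the list alone (median -2.03). Their camera adjusted p was 6.16e-12, or 0.00519 with an estimated correlation. Calcineurin/Crz1 targets were lower in 8 of 11 cases, 8 also adjusted over the list alone (median -1.32), led by the ammonium permease MEP1 at -2.49 ± 0.16. This list had a camera adjusted p of 4.52e-11, or 0.00021 with an estimated correlation. Glucose-repressed genes were lower in 5 of 10 cases, 5 also adjusted over the list alone (median -1.12). Their camera adjusted p was 9.24e-07, or 0.0352 with an estimated correlation. Hsf1 chaperones were lower in 9 of 13 cases, or 10 adjusted over the list alone (camera adjusted p = 2.36e-07, and adjusted p = 0.0506 with an estimated correlation). Of 17 cAMP/PKA components 8 were lower, or 9 adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.0603 with an estimated correlation). GPA2 differed by -2.47 ± 0.21 and YAK1 by -2.30 ± 0.18. Higher at 30 min were 12 of 28 amino acid biosynthesis genes, or 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.91e-09, and adjusted p = 0.131 with an estimated correlation). Ergosterol genes were higher in 8 of 20 cases and lower in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 1.37e-05, and adjusted p = 0.177 with an estimated correlation), with ERG5 at 1.23 ± 0.18. G1/S genes were higher in 3 of 5 cases, 3 also adjusted over the list alone (camera adjusted p = 0.0314, and adjusted p = 0.0506 with an estimated correlation). The PHO regulon was higher in 4 of 13 cases, 4 also adjusted over the list alone (camera adjusted p = 0.000875, and adjusted p = 0.177 with an estimated correlation), with PHO84 at 1.67 ± 0.24. Ribosomal protein genes were lower still in 37 of 111 cases, or 50 adjusted over the list alone (camera adjusted p = 2.51e-09, and adjusted p = 0.29 with an estimated correlation). Their median difference was -0.51, and -0.67 with the coding length trend removed.

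In total 178 genes were higher and 341 lower at 30 min than at 10 min among 2607 tested in wild type, and 194 of these 519 differed at least 2-fold. By scaling, 159 to 237 were higher and 266 to 418 lower. The count ran from 113 to 766 over the pairings of opposite dyes, and was 389 on the larger slide series and 567 with the block. The difference correlated with coding length at a Spearman's rho of -0.345 across genes, which are not independent.

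In the mutant, ribosomal protein genes were lower still at 30 min than at 10 min, and the largest single changes went both ways. FRE1 was higher at 30 min by 2.41 ± 0.21, the zinc transporter ZRT1 by 2.23 ± 0.34, SER3 by 2.01 ± 0.25 and IRC7 by 1.95 ± 0.18. CMK2 was lower, at -2.99 ± 0.28, as were YOR385W (-2.89 ± 0.25), HXT2 (-2.72 ± 0.33) and MEP1 (-2.66 ± 0.16). All of these had adjusted p of 0.000288 or less.

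Ribosomal protein genes were lower at 30 min than at 10 min in 107 of 117 cases in the mutant, or 113 adjusted over the list alone. Their median difference was -1.12, or -1.03 with the coding length trend removed, and RPS22A stood at -1.84 ± 0.24. The list's camera adjusted p was 2.75e-63, or 0.00185 with an estimated correlation. Iron and copper genes were higher in 3 of 12 cases, or 5 adjusted over the list alone (median 0.68). Their camera adjusted p was 0.000109, or 0.000244 with an estimated correlation. Cell wall integrity genes were higher in 7 of 13 cases, or 8 adjusted over the list alone (median 0.75). This list had a camera adjusted p of 2.78e-05, or 0.0288 with an estimated correlation. Calcineurin/Crz1 targets were lower in 7 of 12 cases and higher in 2, or 8 and 2 adjusted over the list alone (median -0.80). Their camera adjusted p was 1.1e-06, or 0.00641 with an estimated correlation. G1/S and S phase genes were higher in 4 of 11 cases, or 5 higher and 1 lower adjusted over the list alone (median 0.42). That list had a camera adjusted p of 0.00414, or 0.00641 with an estimated correlation. MCD1 was higher by 1.65 ± 0.26 and the G1 cyclin CLN2 by 1.54 ± 0.17. STRE targets were lower in 5 of 24 cases, or 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0548).

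Further lists changed with time in the mutant by the preset test and lost the call with an estimated correlation. Ergosterol genes were higher in 8 of 22 cases and lower in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 7.44e-07, and adjusted p = 0.177 with an estimated correlation), with ERG5 at 1.49 ± 0.17. Amino acid biosynthesis genes were higher in 8 of 27 cases, or 16 adjusted over the list alone (camera adjusted p = 7.44e-07, and adjusted p = 0.189 with an estimated correlation). Glucose-repressed genes were lower in 6 of 10 cases, 6 also adjusted over the list alone (camera adjusted p = 0.000214, and adjusted p = 0.123 with an estimated correlation). Of 13 PHO regulon genes 5 were higher, or 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000446, and adjusted p = 0.189 with an estimated correlation). Of 39 ribosome biogenesis genes 7 were higher, or 8 adjusted over the list alone (camera adjusted p = 0.000446, and adjusted p = 0.189 with an estimated correlation). Hsf1 chaperones were lower in 3 of 15 cases, or 8 adjusted over the list alone (camera adjusted p = 0.00414, and adjusted p = 0.331 with an estimated correlation).

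In total 178 genes were higher and 295 lower at 30 min than at 10 min among 2934 tested in the mutant, and 239 of these 473 differed at least 2-fold. Under the scalings 170 to 229 were higher and 170 to 327 lower. Under the pairings of opposite dyes 159 to 641 genes passed, on the larger slide series 300 and with the block 497. The difference correlated with coding length at a Spearman's rho of 0.314 across genes.

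Much of the response was shared by the strains. At 10 min, 305 genes were higher in both, where 88.3 would be given by independent calls. Another 367 were lower in both (93.4 by independent calls), while NSA1 was the 1 gene called in opposite directions. Across the 2361 genes tested in both, the ratios correlated with Pearson's r = 0.876 and Spearman's rho = 0.810, genes not being independent. At 30 min, 503 genes were higher in both (178 by independent calls) and 502 lower in both (143 by independent calls), with 14 called in opposite directions and r = 0.821 and rho = 0.736 across 3978 genes. Of 459 genes that rose in wild type at 10 min and were tested for the difference, 21 were lower in the mutant and 2 higher. Of 520 that fell in wild type, 0 passed the limma test of difference, with 34 at an unadjusted p below 0.05. At 30 min, 5 of 790 genes that rose in wild type were lower in the mutant and 1 higher, and of 738 that fell, 14 were higher and 5 lower. These genes were picked on wild-type arrays that also enter the difference, which by itself favours a smaller change in the mutant.

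In some places a list's median, mean and test differed in sign, and none of these lists passed beyond those already named. In the mutant these were iron and copper genes at 10 min and H+-ATPases at 30 min. For the strain difference at 10 min they were iron and copper, ribosome biogenesis, respiratory chain and histone genes, and at 30 min amino acid, methionine and histone genes. For the change with time they were ribosome biogenesis, methionine, H+-ATPase and histone genes in wild type, and cAMP/PKA components and histones in the mutant.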

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

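The test for compressed ratios on the mutant arrays, the test of missing values among STRE targets and the removal of the coding length trend were chosen only after the result was seen.

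At 10 min the strain difference passed for 23 genes, with a median of -1.26 for STRE targets and -1.63 for trehalose and glycogen genes. Ratios compressed on all mutant arrays, by the authors' normalization or a difference in scale, would lower calcineurin/Crz1 targets too, but their median difference was 0.21, which argues against it. That 1 array alone carries the difference is argued against as well. With each array left out in turn, at least 86.4% of the STRE median difference was left. Still, 10 of 1843 tested genes passed without array 4 of the mutant and 36 of 2337 without array 4 of wild type. The 4 arrays of a group stand for 2 biological replicates, so an array left out may leave another of the same extract. Leaving out single arrays therefore cannot show whether 1 biological replicate carries the difference. STRE targets not tested for lack of values in the mutant had a median rise in wild type higher by 0.93 than the tested ones. Missing values may thus make the tested ones understate the difference. The mutant response of the untested ones is not known, and the mutant's own values set them apart, so this gives no independent support. A contribution of Msn2 and Msn4 to the early rise of these genes stays open as the biological hypothesis. In the mutant 17 of 25 tested STRE targets still rose, with a median of 0.70, so among the tested ones the rise was smaller there rather than absent. As a list they did not pass there in camera with an estimated correlation (adjusted p = 0.221). Whether the factors act on these genes directly was not tested, and the ratios show no difference in level between the strains.

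At 30 min the 29 genes higher in the mutant had a median coding length of 3822 bases and the 11 lower ones of 891, and the difference correlated with coding length at rho = 0.533 over all tested genes with a known length. With the trend removed, the median absolute difference of the 39 of these 40 genes with a known length went from 1.05 to 0.55, so that 52.5% was left, and their median error from 0.210 to 0.180. Among the 3816 of 3978 tested genes with a known length, 43 passed before the removal and 2 after it, because the differences shrank while the errors did not grow. The rho on single arrays was -0.273 and -0.303 on wild-type arrays 1 and 2 and 0.388 and 0.404 on mutant arrays 1 and 2, against 0.117 and -0.046 in wild type and -0.011 and 0.022 in the mutant on arrays 3 and 4. Of the 8 leave-outs 4 gave fewer than 10 genes, namely 0 in limma without array 1 or array 2 of either strain (467 to 658 at an unadjusted p below 0.05), while array 3 of wild type left out gave 259 and array 4 of wild type 73, which neither 1 array alone nor all arrays alike would give. An effect of the strain on long and short transcripts in every replicate would recur on arrays 3 and 4. At 30 min the rho there did not differ between the strains in this way, which argues against it at that time. On arrays 1 and 2 at 30 min the trend with coding length follows the strain. A trend possibly from RNA integrity or labelling can therefore not be told apart there from a strain effect limited to those arrays. At 10 min the rho was 0.279, 0.111, 0.247 and 0.158 on wild-type arrays 1 to 4. On mutant arrays 1 to 4 it was 0.081, -0.078, -0.025 and 0.037. It was thus higher on every wild-type array than on any mutant array, in the direction opposite to 30 min, and the cause was not tested.

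More STRE targets lacked values in the mutant than other genes at 10 min. Of 30 with values on at least 3 wild-type arrays, 8 (26.7%) had fewer than 3 in the mutant, against 301 of 2640 other genes (11.4%), with a two-sided Fisher's exact p of 0.0175, genes not being independent. A lower signal of these genes in the mutant, so that they fell to the authors' filter, may be the reason at 10 min. Lower expression without Msn2 and Msn4 would be the biological form of it. At 30 min the count went the other way, with 35 STRE targets tested in the mutant and 29 in wild type. A lower signal in the mutant at both times would not give that. The deleted genes themselves had values in the mutant, MSN2 on all 8 arrays and MSN4 on 5, which a filter that removed every gene lacking a transcript would not give unless their probes measured other RNA. Signal intensities were not used here, so a loss of spots for other reasons stays open.

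Other splits of the arrays were counted for each comparison. They treat the arrays as independent, but each group holds 2 biological replicates, and the 4 replicates of 2 groups allow 3 splits, too few for a share under 0.05. For KOH against KCl each group allowed 8 sign assignments of its 4 arrays, also too few, and in each group 1, the real one, gave as many genes. The real counts were 1140 and 1109 in wild type and mutant at 10 min and 1630 and 1742 at 30 min, and the highest others 122, 143, 13 and 20. For the strain difference at 10 min 1 of 35 splits gave as many genes (23, highest other 5), for time in wild type 1 of 35 (519, highest other 28) and for time in the mutant 1 of 35 (473, highest other 2). For the strain difference at 30 min 2 of 35 splits gave as many, the real one with 40 and another with 102. That split set arrays 1 and 2 of both strains against arrays 3 and 4, which points to a structure of the samples, and it was the highest other split in all 4 of these comparisons.

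The test of the strain difference at 10 min passed for VHT1 (1.10), ARG3 (0.92), PGM2 (-2.75), MSC1 (-2.20), GLC3 (-2.02), TPS2 (-1.95), HXK1 (-1.92), STF2 (-1.87), NSA1 (-1.75) and GSY2 (-1.63). At 30 min it passed for USO1 (1.81), PRP8 (1.52), NUP188 (1.38), TOM1 (1.35), YOR289W (-1.28), RPL22A (-1.17), PYK2 (-1.15) and RPL25 (-1.12).

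Between 10 and 30 min, the test of the difference passed for 519 genes in wild type. Among them were SER3 (2.18), SNZ1 (1.97), HPT1 (1.92), OPI3 (1.81), BDH2 (-4.22), GSY1 (-3.68), YOR385W (-3.30) and HXT2 (-3.20). List medians differed by -1.36 for STRE targets, -2.03 for trehalose and glycogen, -1.32 for calcineurin/Crz1 targets and -1.12 for glucose-repressed genes. In the mutant it passed for 473 genes, among them FRE1 (2.41), ZRT1 (2.23), SER3 (2.01), IRC7 (1.95), CMK2 (-2.99), YOR385W (-2.89), HXT2 (-2.72) and MEP1 (-2.66). List medians differed there by -0.80 for calcineurin/Crz1 targets, 0.68 for iron and copper, 0.75 for cell wall integrity, -1.12 for ribosomal proteins and 0.42 for G1/S genes.

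Single arrays stood apart from the other 3 of their group in 13 of 340 groups tested by Dixon's ratio, the gap to the nearest array over the range. Its nominal rate by chance is about 1 in 20 groups, which was not measured here. In wild type at 10 min the deposited median of array 2 was 0.262 against -0.102 to -0.064 on the others, and TRM8 stood at -6.53 on it against -1.19 to -0.87. On array 3 of that group RLP24 stood at -2.55 (others -1.59 to -1.44), PMA1 at -0.51 (others -0.84 to -0.80), CTT1 at 1.17 (others 0.23 to 0.39) and PHO84 at -0.20 (others -1.14 to -1.08), and on array 4 CCP1 stood at 0.51 (others 0.88 to 0.90). In the mutant at 10 min array 1 had a deposited median of -0.285 (others -0.0215 to 0.002) and ARG3 at 2.36 (others 1.92 to 1.97). In wild type at 30 min the median of glucose-repressed genes was 0.86 on array 3 (others 0.19 to 0.22), ALD4 1.15 on array 4 (others 1.65 to 1.74) and MSN2 0.21 on array 2 (others -0.32 to -0.30). In the mutant at 30 min YRO2 stood at -4.00 on array 3 (others -2.77 to -2.52).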

How the results depend on the processing

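Centring on the genes measured on all 16 arrays and removal of the coding length trend were chosen only after the result was seen. No paired analysis was possible from the labels alone because they give the arrays no replicate numbers, so arrays of opposite dye were averaged under each of the 16 possible pairings. Counts of genes or lists stayed within 1.5 times in 249 cases and left that range in 59. The averaged pairings and the 2-fold minimum entered these counts but not the tallies of named genes and single lists that follow. Those tallies therefore do not show which named genes kept their call with 2 replicates per group. Named genes kept direction and side of the threshold in 8817 cases, kept the direction but no longer passed in 587, and reversed in 0. For single lists 2440 results were the same, 69 newly passed, 117 no longer passed and 2 reversed. The latter were the ribosomal protein median of the strain difference at 10 min, 0.14, which was 0.00263 under scale normalization and -0.0152 with the coding length trend removed, and the cause was not tested. Centring on the genes measured on all 16 arrays moved the median of all genes in wild type at 10 min by 0.105 in log2.

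A 2-fold minimum left 341 and 279 genes in wild type and mutant at 10 min, 481 and 505 at 30 min, 25 for the strain difference at 30 min, and 194 and 239 for time in wild type and mutant. The overlap of the strains became 152 genes at 10 min and 301 at 30 min, as a stricter threshold must give fewer. Opposite dyes averaged, which leaves 2 replicates per group, gave at the lowest pairing 666 and 483 genes at 10 min and 689 and 601 at 30 min. For the strain differences at 10 and 30 min it gave 4 and 0 (in limma, with 274 to 673 at an unadjusted p below 0.05 under the pairings with 0), and for time 113 and 159. The highest pairing gave 252 for the strain difference at 30 min. The larger slide series alone, with fewer arrays, gave 668 of 2046 genes tested in the mutant at 10 min and 300 of 2004 for time in the mutant. For the strain difference it gave 8 of 1834 at 10 min and, in limma, 0 of 3830 at 30 min (799 at an unadjusted p below 0.05). The compared groups alone, with fewer arrays behind the error, gave 810 in the mutant at 30 min, 13 for the strain difference at 10 min and 0 at 30 min (673 at an unadjusted p below 0.05).

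The strain difference at 10 min also had 35 genes under scale and 15 under quantile normalization, 13 among genes on all 4 arrays and 47 among genes on at least 2. At 30 min it had 86 on the values as deposited, 26 under scale and 98 under quantile normalization, 116 among genes on all 4 arrays, 220 with array weights and 2 with the coding length trend removed. The cause was not tested, except that the trend's removal shrank the differences.

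Leaving out arrays in turn gave 647 to 892 genes in the mutant at 10 min. Without its array 4, 647 of 2049 tested genes passed, while 892 of 3007 passed without its array 1. The strain difference at 10 min ran from 10 of 1843 tested, without array 4 of the mutant, to 36 of 2337, without array 4 of wild type. At 30 min it ran from 0 to 259 in limma: 0 without array 1 or 2 of either strain (467 to 658 at an unadjusted p below 0.05), 259 without array 3 of wild type and 73 without its array 4. The lists past the threshold there ran from 4 to 8, with 4 without array 3 of wild type, array 3 of the mutant or array 4 of the mutant. Fewer arrays were left each time. Without array 4 of the mutant at 10 min far fewer genes could also be tested, which by itself lowers the counts. Why some arrays moved the counts more was otherwise not tested.

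With an estimated correlation the lists past the threshold became 3 in the mutant at 10 min, 4 in wild type and 4 in the mutant at 30 min, 2 for the strain difference at 10 min and 0 at 30 min (3 at an unadjusted p below 0.05). For time they became 4 in wild type and 5 in the mutant. By construction a higher correlation widens the error of a list. The rotation test (fry) passed 15 lists in wild type at 10 min, 2 for the strain difference at 10 min and 0 at 30 min (5 at an unadjusted p below 0.05), on the genes with values on all 16 arrays. Under scale and under quantile normalization 3 and 3 lists passed for the strain difference at 30 min, and the cause was not tested. The share of genes with values limits what could be tested, and signal over background was not used here.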

Other observations

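ENA1, the main sodium pump gene, had too few values for a test in any group. Its single values were 3.25 in wild type and 3.01 in the mutant at 10 min and 0.68 in the mutant at 30 min, and none was present in wild type at 30 min.

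After the group mean and the dye term were taken out, the residuals of arrays 1 and 2 and of arrays 3 and 4 correlated with each other. Over 1477 genes, which are not independent, the mean correlation within these pairs was 0.257 in wild type and 0.177 in the mutant at 10 min, and 0.509 and 0.570 at 30 min. The other pairing of opposite dyes gave -0.465, -0.495, -0.659 and -0.720, and is not independent of the first, since residuals of a group add up to near 0. Which arrays carry the same extracts is not stated in the labels. With arrays 1 and 2 and arrays 3 and 4 averaged in every group, 666 and 483 genes passed for KOH against KCl at 10 min and 689 and 601 at 30 min. The strain difference then passed for 5 genes at 10 min, with 4 of 22 STRE targets lower, and for 0 at 30 min in limma (274 at an unadjusted p below 0.05).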
